A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

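The series measured gene expression in the budding yeast Saccharomyces cerevisiae, strain BY4741, in the wild type and in rlm1 and swi3 mutants, with and without 30 µg/ml Congo Red for 4 hours. Congo Red is a dye that binds chitin and glucan in the cell wall and disturbs its assembly. Rlm1 is a transcription factor at the end of the cell wall integrity MAP kinase pathway, and Swi3 is a subunit of the SWI/SNF chromatin remodelling complex. Each of the 6 groups held 3 arrays, which the series design describes as separate biological samples. Total RNA was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols.

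The deposited values are log2 probe set summaries, and the submitters' processing notes name GCRMA, which corrects background by probe sequence, normalizes arrays and summarises probes. Its version, the arrays normalized together and any filter were not given in the sources used here. The log2 scale was read from the range of the values. The 18 arrays did not share a common distribution in the deposited table. GCRMA normalizes arrays before it summarises probes, so this alone does not show whether they were normalized together. Scanner files were not used here, so scan dates and batches were not examined.

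Of 5814 probe sets, 98 controls were left out of the tests (51 Affymetrix controls and 47 reporter probe sets). Of the other 5716 probe sets, 5498 had 1 gene symbol in the platform annotation, 218 had none and 0 had several. Symbols were updated through gene identifiers in the NCBI table of assembly R64, which changed 12 of them. For a gene with several probe sets, the probe set with the highest mean over all arrays was kept, which dropped 49. Features had to reach a log2 value of 4 on at least 3 of the 18 arrays, which removed 8 and left 5659 features, 5442 of them with a gene name. No genome coordinates are given, because the deposited table and its labels name no build, and assembly R64 was used only for names and for which genes neighbour each other. The number of arrays, 3 per group, limits the precision. No 2 arrays held identical values: at least 95.3% of the probe sets differed between any 2 of them.

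Group means were fitted on all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and 8 contrasts were taken: Congo Red against none in each strain, the difference of this response between each mutant and the wild type and between the mutants, and each mutant against the wild type without the dye. P-values were adjusted by the Benjamini-Hochberg method over the 5659 features, and a call needed an adjusted p under 0.05. Changes are given as log2 differences with the fit's SE, n = 3 arrays per group. Calls of at least 2-fold are counted beside them. All these choices were fixed before the data were examined. Of the 47 reporter probe sets, 36 stayed under a level of 7 on every array, so a change to or from a lower level is a least estimate, and a difference of responses with such a level has an uncertain size (7 was set after the values were seen).

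The replicate numbers in the sample titles were checked for pairing. Deviations from the group mean correlated between untreated and treated arrays of the same number within every strain (r from 0.419 to 0.909 across genes), and the correlations between strains ranged from -0.195 to 0.670. Between different numbers, r was at most 0.413 in the wild type and -0.104 in swi3. In rlm1 it was 0.871 and 0.765 between numbers 2 and 3, close to the values within them (0.852 and 0.837), so there the check shows only that number 1 stands apart. Same-numbered arrays of a strain were treated as pairs, since every same-number r was above 0.1, from this check and not from a statement in the labels. Some different numbers in the wild type and rlm1 also passed 0.1, so this bound does not tell pairs from other arrays. Wild-type untreated number 2 had an r of 0.4545 with treated number 2 and 0.413 with treated number 1. The pairing is thus an assumption on which all pair-blocked counts rest. The replicate block, called the pair-blocked fit below, has a term for each pair within a strain and was added after seeing the data. Its values are given for some named genes whose call they change. They are also given where a count of calls moves by over 1.5 times, except for lists with at most 4 added calls. Of 249 tests of named genes not called in the planned fit, the pair-blocked fit called 108, not all of which are printed. Pairs lie within a strain, so the untreated comparisons between strains have no such fit.

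The 25 gene lists fixed before the data were examined covered Rlm1-linked targets, signalling, chitin, beta-glucan, mannoproteins, general and osmotic stress, ribosome biogenesis, ribosomal proteins, nutrient regulons, mating, cell separation, the SWI/SNF complex, other pathways, genes deleted in BY4741 and markers of mating type alpha and sporulating cells. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks only whether a list's genes move one way on balance. Adjusted p-values of each method cover all 200 tests. The deleted genes and both sets of markers served as checks, for genes absent from the strain and for cells of other types. With an estimated correlation 0 of the 200 tests passed, against 83 with the preset value.

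The named genes are RLM1 and SWI3, for each comparison up to 10 higher and 10 lower called genes with the largest change whose arrays do not overlap (this last condition was not used for differences of responses), and for each list up to 4 called members with the largest change, or up to 2 members where none was called. Genes outside this rule are said to be so. Alternatives were other filters, other scaling, other variance models, every probe set as its own feature, the replicate number as a block and leaving out each array in turn. A pseudocount was not tried, because the values were already logarithms. Fits without both arrays of rlm1 number 1 were added after seeing the data.

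The fits were tested on simulated data for Congo Red in wild type: 200 of 5659 genes were changed, and the noise had the spread left after the pair terms. The planned fit recovered 58.0% of the 100 genes changed by 1 log2 unit and 95.0% of the 100 changed by 2, with 0 false calls among 153. The pair-blocked fit recovered 98.0% and 100%, with 8 false calls among 206. The simulated values held the pair terms that this fit assumes, so its higher recovery was built in. It does not test whether the pairs are real. Overlaps between comparisons that share the wild-type arrays were set against 100 simulations of unchanged groups. The counts of responders lower in the mutants were set against 100 simulations in which all strains had the wild-type response. Smaller changes in the mutants were also counted against a left-out wild-type pair. Both were added after seeing the data. In these simulations the noise of each gene was drawn by itself, so deviations shared by the genes of an array were left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.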

Results

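Expression was measured in 18 cultures of budding yeast: the wild type, an rlm1 mutant and a swi3 mutant, each without and with 30 µg/ml Congo Red for 4 hours, with 3 arrays in each of the 6 groups. The median log2 level of an array was between 10 and 10.03 in the wild type and between 9.58 and 9.70 in swi3. In rlm1 it was 9.27 and 9.28 on the number 1 arrays and between 9.98 and 10.02 on the other arrays. The median within-group SD was 0.10 and 0.11 in the wild-type groups, 0.41 and 0.42 in rlm1, and 0.14 and 0.15 in swi3. The number 1 arrays of rlm1 also had larger differences between 3' and 5' control probe sets (1.15 and 1.03) than the other rlm1 arrays (at most 0.86). The planned fit uses 1 estimate of the spread for all arrays, and values without these arrays, chosen after seeing the data, are given beside its counts.

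RLM1 and SWI3 were low on the arrays of their own mutants. RLM1 had a log2 level of 9.26 ± 0.12 (SD, n = 3) in the untreated wild type and 4.78 ± 0.12 in untreated rlm1. With Congo Red it was 10.44 ± 0.08 in the wild type, 4.82 ± 0.27 in rlm1 and 10.45 ± 0.16 in swi3, where the untreated level was 9.94 ± 0.03. SWI3 was at 9.55 ± 0.12 and 9.54 ± 0.10 in the wild type without and with the dye, 9.28 ± 0.64 and 9.35 ± 0.83 in rlm1, and 3.26 ± 0.11 and 3.37 ± 0.13 in swi3.

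**Figure D1:**
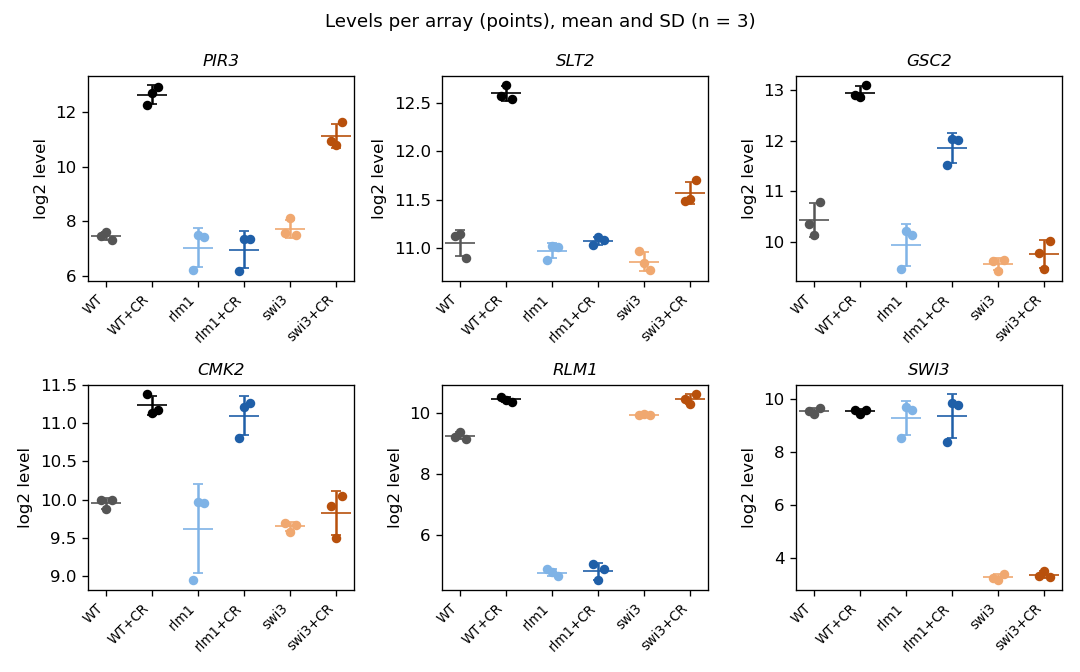
Log2 levels of 6 genes on each of the 18 arrays (points) with the group mean and SD (bars, n = 3); CR is 30 µg/ml Congo Red. PIR3 averaged 12.62 in the treated wild type, 6.97 in treated rlm1 and 11.12 in treated swi3, while GSC2 averaged 12.96, 11.85 and 9.75 in the same groups.

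The treated and untreated wild type were compared for the response to Congo Red. PIR3, a cell wall protein with internal repeats, rose the most, by 5.16 ± 0.37 (SE, n = 3) on the log2 scale (adjusted p = 6.1e-07). KDX1, a kinase-like protein of the cell wall integrity pathway, rose by 3.86 ± 0.31, and BAG7, a GTPase-activating protein for Rho1, rose by 3.04 ± 0.17. GSC2, the stress-induced glucan synthase subunit, rose by 2.53 ± 0.23, and YPS3, a cell surface aspartic protease, rose by 2.70 ± 0.22. CRG1 (3.18), YPL088W (2.93), SRL3 (2.78), HSP12 (2.55) and PLN1 (2.47) completed the 10 named genes with the largest increases, all with an adjusted p of 0.014 or lower. The untreated level of BAG7 was 5.45, under 7, so its rise is a least estimate, as are those of RTA1, HXT5 and SPO11 below and the fall of YLR154C-H. The 10 named genes with the largest decreases were APE1, a vacuolar aminopeptidase (-1.88 ± 0.38, adjusted p = 0.013), YLR154C-H (-1.83), the peptide transporter OPT1 (-1.23), HMS2 (-1.12), the malic enzyme MAE1 (-1.12), the phospholipase PLB2 (-1.04), the adenine deaminase AAH1 (-0.94), ATO3 (-0.90), RKI1 (-0.87) and the RNA helicase DHR2 (-0.85).

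Of 22 measured Rlm1-linked cell wall integrity targets, 16 were higher and 0 lower in the treated wild type (19 higher adjusted over the list alone, 22 in the pair-blocked fit), with a median change of 1.21. The camera test gave adjusted p = 3.6e-45, against adjusted p = 0.087 with an estimated correlation, and fry gave adjusted p = 1.25e-04. Among the signalling components of the pathway, 6 of 28 rose (7 adjusted over the list alone, 12 higher and 1 lower in the pair-blocked fit), including the MAP kinase SLT2 (1.54) and the phosphatase PTP2 (1.41). The list's adjusted p was 5.5e-08, and adjusted p = 0.782 with an estimated correlation. Chitin genes rose in 5 of 17 cases (6 adjusted over the list alone, 8 higher and 1 lower in the pair-blocked fit), among them GFA1, which makes glucosamine 6-phosphate for chitin (1.23), the synthases CHS1 (1.12) and CHS3 (0.84), and PCM1 (1.03). The list's adjusted p was 1.1e-05, and adjusted p = 0.758 with an estimated correlation. Mannoproteins of the wall rose in 7 of 24 cases (11 adjusted over the list alone, 15 higher and 5 lower in the pair-blocked fit), such as PST1 (1.86) and the protease YPS6 (1.46). Mannoproteins as a list had adjusted p = 2.1e-08 and adjusted p = 0.770 with an estimated correlation. Beta-glucan genes rose in 3 of 31 cases (7 adjusted over the list alone, 16 higher and 5 lower in the pair-blocked fit): GSC2, the transglycosylase CRH1 (1.31) and ROT1 (0.77). For beta-glucan genes camera gave adjusted p = 1.6e-05 and adjusted p = 0.963 with an estimated correlation.

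Outside the wall, 3 of 41 ribosome biogenesis genes fell in the wild type (27 adjusted over the list alone, 37 in the pair-blocked fit): DBP2 (-0.75), RRP5 (-0.68) and RPA135 (-0.52). The median of the 41 was -0.47. Ribosome biogenesis as a list had adjusted p = 2.2e-25 and adjusted p = 0.648 with an estimated correlation. General stress genes had a median of 0.48 with 1 of 34 called, HSP12 (3 adjusted over the list alone, 23 in the pair-blocked fit). The general stress list had adjusted p = 2.6e-08 and adjusted p = 0.829 with an estimated correlation. Osmotic stress genes rose in 2 of 14 cases, HSP12 and RTC3 (1.86) (5 adjusted over the list alone, 10 higher and 1 lower in the pair-blocked fit). The osmotic stress list had adjusted p = 2e-06 and adjusted p = 0.758 with an estimated correlation. Amino acid biosynthesis had 0 of 39 calls (3 lower adjusted over the list alone, 2 higher and 21 lower in the pair-blocked fit). The amino acid list had adjusted p = 3.8e-05 and adjusted p = 0.988 with an estimated correlation. LEU9 was at -1.02 ± 0.29. Ribosomal proteins had 0 of 128 calls (20 lower in the pair-blocked fit), with a median of -0.08, adjusted p = 1.6e-05 and adjusted p = 0.988 with an estimated correlation.

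In the other lists at most 1 member rose in the planned fit. It was called among mating genes (MSG5 1.06, of 24), the phosphate regulon (GDE1 1.14, of 17), glucose-repressed genes (HXT5 0.95, of 30), drug efflux genes (RTA1 1.86, of 21) and markers of sporulating cells (SPO11 1.65, of 22). None of 12 SWI/SNF subunits, 19 inositol and phospholipid genes, 26 cell cycle genes of G1 and S phase, 14 daughter-separation genes, 19 sulphur genes, 20 iron uptake genes, 22 genes of the unfolded protein response, 34 oxidative phosphorylation genes, 4 markers of alpha cells and 3 genes deleted in BY4741 was called by limma in the planned fit, where 590 of all 5659 features had an unadjusted p under 0.05. Adjusted over the list alone, 1 drug efflux gene and 1 cell cycle gene were also lower. In the pair-blocked fit, 13 oxidative phosphorylation genes, 9 genes of the unfolded protein response and 13 glucose-repressed genes were higher, with 1 lower in each list. That fit also had 9 iron uptake genes and 8 drug efflux genes lower, with 2 higher in each. Higher and lower calls there were 3 and 2 for mating, 4 and 3 for phosphate, 3 and 3 for inositol, 5 and 5 for cell cycle, 2 and 4 for separation, 4 and 3 for sulphur, 5 and 1 for sporulation markers, 1 and 1 for SWI/SNF, and 0 and 1 for alpha markers. Camera passed for oxidative phosphorylation (adjusted p = 0.0024, and adjusted p = 0.988 with an estimated correlation) and for glucose-repressed genes (adjusted p = 0.0091, and adjusted p = 0.984 with an estimated correlation).

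In all, 89 features were higher and 27 lower in the treated wild type (66 and 6 by at least 2-fold). The pair-blocked fit called 953 higher and 903 lower, and 100 and 8 by at least 2-fold. A further quantile normalization moved the share of lower calls from 23.3% to 51.2% (479 higher, 503 lower), and centring of the arrays moved it to 43.3%. Leaving out any of the 6 wild-type arrays lowered the total from 116 to between 62 (without untreated number 3) and 74 (without treated number 2), whereas leaving out both number 1 arrays of rlm1 raised it to 1061. Without any 1 of the 6 wild-type arrays the higher calls were 57 to 65 and the lower calls 5 to 10, and the lower calls were 42 with the trended and robust prior and 41 with ordinary least squares. Of the genes named for the wild type, APE1, YLR154C-H, OPT1, HMS2, PLB2, DHR2, HSP12, CHS1, ROT1, DBP2, RPA135, RRP5, HXT5 and SPO11 lost their call without at least 1 of these arrays. HXT5 was also not called after quantile normalization (adjusted p = 0.069) or with the trended and robust prior (0.074), nor DBP2 after centring (0.064). With ordinary least squares HXT5 (adjusted p = 0.0526) and YLR154C-H (0.051) were not called.

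In the rlm1 mutant, 5 features rose with Congo Red, all by at least 2-fold and all also higher in the wild type. By limma 0 fell, with 67 features in all at an unadjusted p under 0.05. The named genes were GSC2 (1.91 ± 0.23, n = 3, adjusted p = 7.1e-04), DIA1, linked to invasive growth (1.75 ± 0.19), the calmodulin-dependent kinase CMK2 (1.48 ± 0.23) and YSR3, a phosphatase of sphingoid base phosphates (1.34 ± 0.18). The last was a probe set with no gene name here (2.13). These calls rest on the spread shared with the other strains: fitted on the rlm1 arrays alone, 0 were called (adjusted p = 0.646 for GSC2 and DIA1). CMK2 was also not called with ordinary least squares (adjusted p = 0.054) or without treated number 2 or 3 (0.120 and 0.127). PIR3 was at -0.08 ± 0.37, KDX1 at 0.19 and SLT2 at 0.10 (chosen here after their wild-type values were seen).

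Of the 22 Rlm1-linked targets, only GSC2 passed in rlm1 in the planned fit (2 adjusted over the list alone, 2 higher and 1 lower in the pair-blocked fit), and the median was 0.09. Camera gave adjusted p = 4.5e-06, against adjusted p = 0.829 with an estimated correlation and 0.802 by fry. GSC2 was also the only call of the planned fit among 31 beta-glucan genes, against 2 higher in the pair-blocked fit (camera adjusted p = 0.0021, and adjusted p = 0.988 with an estimated correlation). Ribosome biogenesis had 0 of 41 calls in either fit and a median of -0.06. For this list camera gave adjusted p = 0.0095, and adjusted p = 0.988 with an estimated correlation. The direction of the list turned without rlm1 untreated number 1 (camera adjusted p = 0.637). General stress had 0 of 34 calls in either fit and a median of -0.03. Below the threshold of the planned fit, PHO89 was at 1.42 ± 0.44, RTA1 at 1.44 ± 0.27 and YPS1 at 1.04 ± 0.24, and each was called in the pair-blocked fit (adjusted p = 5.5e-05, 8.3e-04 and 3.9e-04). That fit called 79 higher and 20 lower, with 2 mannoproteins higher and 3 lower, 3 cell cycle genes higher, and 1 drug efflux gene higher and 2 lower. Without treated number 1 the planned total was 9, and without both number 1 arrays it was 20.

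In the swi3 mutant, the difference between 3' and 5' control probe sets was 1.04, 0.83 and 1.26 on the untreated and 0.80, 0.80 and 0.87 on the treated arrays, against means of 0.775 and 0.748 in the wild type. The 25S ribosomal RNA probe sets went from 11.58 and 10.74 to 7.97 and 7.13 in swi3. They also fell, but by less, in the wild type (from 10.04 and 9.76 to 8.94 and 8.70). The same held in rlm1 (from 12.95 and 12.74 to 12.03 and 11.61). Part of the changes with the dye in swi3, and of their differences from the other strains, may therefore come from RNA quality. By limma 9 features rose, 6 of them by at least 2-fold, and all 9 were also higher in the wild type. By limma 0 fell, with 121 features in all at an unadjusted p under 0.05. The features that rose were PIR3 (3.38 ± 0.37, n = 3, adjusted p = 7.8e-04), KDX1 (1.87 ± 0.31), PST1 (1.80 ± 0.23), YPS3 (1.32 ± 0.22), BAG7 (1.18 ± 0.17, with both groups under a level of 7), the kinase YPK2 (0.96 ± 0.18), YPL088W (0.89 ± 0.16), SLT2 (0.71 ± 0.12) and a probe set with no gene name here (1.45). Of the named genes, only PIR3 and PST1 kept their call without each of the 6 swi3 arrays in turn and on the swi3 arrays alone. BAG7 was not called after quantile normalization (adjusted p = 0.549) or centring (0.112), SLT2 after centring (0.129), and YPK2 after quantile normalization (0.113) or with the trended and robust prior (0.097). With ordinary least squares KDX1 (adjusted p = 0.0555), YPS3 (0.0523) and YPK2 (0.0555) were not called. GSC2 was at 0.20 ± 0.23, CMK2 at 0.17 and YSR3 at -0.12 (chosen after their values in the other strains were seen).

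Of the 22 Rlm1-linked targets, 4 rose in swi3 (13 adjusted over the list alone, 18 in the pair-blocked fit) with a median of 0.52, and fry gave adjusted p = 0.025. Camera gave adjusted p = 3.6e-45, and adjusted p = 0.087 with an estimated correlation. Signalling components rose in 3 of 28 cases (5 adjusted over the list alone, 10 in the pair-blocked fit). Signalling components as a list had adjusted p = 1.1e-08 and adjusted p = 0.758 with an estimated correlation. Mannoproteins rose in 3 of 24 (5 higher and 1 lower adjusted over the list alone, 10 and 1 in the pair-blocked fit). The mannoprotein list had adjusted p = 6.3e-10 and adjusted p = 0.758 with an estimated correlation. Chitin genes had 0 of 17 calls (0 adjusted over the list alone, 8 higher in the pair-blocked fit, including CHS1 at 0.53 and PCM1 at 0.55). The chitin list had adjusted p = 2.2e-05 and adjusted p = 0.770 with an estimated correlation. General stress had 0 of 34 calls in either fit, and ribosome biogenesis had 0 of 41 (3 lower in the pair-blocked fit) with a median of -0.14, adjusted p = 1.0e-13 and adjusted p = 0.758 with an estimated correlation. The pair-blocked fit called 335 features higher and 74 lower in swi3, with 4 beta-glucan genes higher and 1 lower, 6 oxidative phosphorylation genes higher and 3 sporulation markers higher. Leaving out any of the 6 swi3 arrays lowered the 9 calls to between 3 (without untreated number 1) and 5 (without untreated number 2), and leaving out both rlm1 number 1 arrays raised them to 138.

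The test of the difference between rlm1 and the wild type asked how far the response rests on Rlm1. By limma 18 features had a lower response in rlm1, 16 of them by at least 2-fold, and 0 a higher one, with 186 in all at an unadjusted p under 0.05. Among named genes, the largest differences were in PIR3 (-5.24 ± 0.52, n = 3 per group, adjusted p = 7.7e-05), KDX1 (-3.67 ± 0.44), BAG7 (-2.86 ± 0.24), YPL088W (-2.62 ± 0.22), SHH3 (-1.98 ± 0.26), YNR066C (-1.98 ± 0.31), PRM10 (-1.93 ± 0.36), YPK2 (-1.90 ± 0.25), PST1 (-1.79 ± 0.32) and YPS3 (-1.78 ± 0.32). Mean levels under 7 enter the differences of PIR3 (6.97 in treated rlm1), BAG7, SHH3, YNR066C and RLM1, so the sizes and the order of these are uncertain. The wall protein CWP1 (-1.54), SLT2 (-1.44), CRH1 (-0.94) and the phosphatase MSG5 (-0.93) were also called. RLM1 itself (-1.15) is among the 18, but its deletion fixes that difference, and 17 calls remain without it. Among these, YPL088W neighbours RLM1 in assembly R64, and an effect of the deletion on its neighbour was not tested. PRM10, PST1, YPS3, CWP1, CRH1 and MSG5 lost their call in the fit of the 2 strains alone and without at least 1 of the 12 arrays. YNR066C lost it after quantile normalization (adjusted p = 0.052). MSG5 was also not called after centring (adjusted p = 0.0565) or with the trended and robust prior (0.0576). With ordinary least squares CWP1 (adjusted p = 0.0522) and PRM10 (0.0665) were not called.

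The response of 7 of the 22 Rlm1-linked targets was lower in rlm1 (15 adjusted over the list alone, 19 in the pair-blocked fit), or 6 of 21 without RLM1 (18 in the pair-blocked fit), with a median difference of -0.94 over the 22 and fry's adjusted p = 0.0089. Camera gave adjusted p = 1.6e-52, and adjusted p = 0.087 with an estimated correlation. The response was also lower in 5 of 28 signalling components, or 4 of 27 without RLM1 (for the 28, 6 adjusted over the list alone, 8 in the pair-blocked fit, adjusted p = 4.9e-10, and adjusted p = 0.758 with an estimated correlation) and 4 of 24 mannoproteins (7 adjusted over the list alone, 11 in the pair-blocked fit, adjusted p = 1.45e-14, and adjusted p = 0.674 with an estimated correlation). General stress genes had 0 of 34 calls (2 lower adjusted over the list alone, 13 lower in the pair-blocked fit). General stress as a list had adjusted p = 2.8e-12 and adjusted p = 0.758 with an estimated correlation. HSP12 was at -2.79 ± 0.73 (pair-blocked adjusted p = 1.9e-05) and DDR2 at -1.55 ± 0.42. Ribosome biogenesis had 0 of 41 calls (0 adjusted over the list alone, 23 higher in the pair-blocked fit), with a median of 0.41, adjusted p = 4.4e-25 and adjusted p = 0.648 with an estimated correlation. The pair-blocked fit called 268 features higher and 328 lower, with 7 chitin genes lower and 1 higher, 8 beta-glucan genes lower and 1 higher, 6 glucose-repressed genes lower, and 9 amino acid genes and 4 iron uptake genes higher. Quantile normalization gave 70 higher and 130 lower, so 65.0% lower in place of 100%. The planned total was 9 without wild-type untreated number 3, wild-type treated number 3 or rlm1 untreated number 2, 10 without wild-type treated number 2 or rlm1 untreated number 3, 11 without the untreated or the treated wild-type number 1, 53 without rlm1 untreated number 1 and 170 without both number 1 arrays of rlm1.

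Between swi3 and the wild type, 6 features had a lower response in swi3, all by at least 2-fold, and by limma 0 a higher one, with 108 in all at an unadjusted p under 0.05. The lower responses were in GSC2 (-2.33 ± 0.32, n = 3 per group, adjusted p = 0.0034), YPL088W (-2.05 ± 0.22), YSR3 (-1.92 ± 0.26), BAG7 (-1.86 ± 0.24), and 2 probe sets with no gene name here (-2.0 and -1.58). BAG7 was under 7 in both swi3 groups and the untreated wild type, so the size of its difference is uncertain. The shift in the 3' to 5' difference within swi3 does not cancel in this test. PIR3 was at -1.78 ± 0.52 and HSP12 at -2.27 ± 0.73, below the threshold in the planned fit and called in the pair-blocked fit (adjusted p = 0.020 and 2.0e-04). HSP12 was among the named genes with the largest increases in untreated swi3 (below), so its smaller response need not mean a lower treated level. Of the named calls, BAG7 was not called after centring (adjusted p = 0.0503).

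Of the 22 Rlm1-linked targets, only GSC2 passed in this test (7 adjusted over the list alone, 14 in the pair-blocked fit), and the median was -0.64. Camera gave adjusted p = 3.9e-31, against adjusted p = 0.243 with an estimated correlation and 0.158 by fry. General stress had 0 of 34 calls (0 adjusted over the list alone, 7 lower in the pair-blocked fit) and a median of -0.52. For general stress camera gave adjusted p = 5.6e-18 and adjusted p = 0.726 with an estimated correlation. Sulphur genes had 0 of 19 calls (0 adjusted over the list alone, 6 lower in the pair-blocked fit, among them MET14 at -0.98 and MET3 at -0.91). The sulphur list had adjusted p = 6.7e-05 and adjusted p = 0.829 with an estimated correlation. The pair-blocked fit called 86 features higher and 169 lower, with 6 signalling components, 5 beta-glucan genes, 4 chitin genes and 6 osmotic stress genes lower, 6 mannoproteins lower and 2 higher, and 5 ribosome biogenesis genes higher. Quantile normalization gave 16 higher and 84 lower, so 84.0% lower in place of 100%. Without both number 1 arrays of rlm1 the total was 103.

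Set against each other, the responses of the mutants differed in 1 feature: PIR3 responded more in swi3 than in rlm1 (3.46 ± 0.52, n = 3 per group, adjusted p = 0.041, but 0.533 in the fit of the 2 mutants alone and 0.189 with ordinary least squares). Its level of 6.97 in treated rlm1 was under 7, so the size is uncertain. By limma 0 responded less, with 54 features in all at an unadjusted p under 0.05. The pair-blocked fit called 73 features higher in swi3 and 28 lower. KDX1 (1.67, pair-blocked adjusted p = 0.0093) and BAG7 (1.00, 0.018) were on the higher side, as were 12 of 22 Rlm1-linked targets (1 lower), 9 of 24 mannoproteins and 5 of 17 chitin genes (1 lower) in that fit. GSC2 (-1.71, pair-blocked adjusted p = 0.0018), PHO89, a phosphate transporter (-1.33, 0.0022), and DSE4, a daughter-separation glucanase (-0.70, 0.0093), were on the lower side. Quantile normalization gave 11 higher and 6 lower. The planned fit had 0 calls without any of the 6 swi3 arrays or of the number 2 and number 3 arrays of rlm1, 2 without rlm1 untreated number 1, 4 without rlm1 treated number 1 and 13 without both.

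The 66 features that rose at least 2-fold in the wild type changed by a median of 1.49 there, 0.21 in rlm1 and 0.57 in swi3. In the planned fit, 18 had a lower response in rlm1 and 6 in swi3, and by limma 0 had a higher response in either mutant, in the planned or the pair-blocked fit. In the pair-blocked fit, 57 had a lower response in rlm1 and 58 in swi3: 50 were lower in both mutants, 7 in rlm1 alone, 8 in swi3 alone and 1 in neither. Both differences share the wild-type arrays used for the selection, which favours lower responses in the mutants. In 100 simulations with the wild-type response in all strains, a mean of 0.02 and at most 1 were lower in both, of a mean of 83.2 responders. The simulations left out deviations that the genes of an array share, so they may understate the joint calls that arise by chance. With the genes selected on 2 wild-type pairs and set against the left-out pair alone, 37 of 39, 34 of 35 and 31 of 32 had smaller changes in both mutants. In the simulations, a mean of 32.15 and at most 43 had smaller changes in both, but there all wild-type pairs served for selection and comparison. Against a left-out pair the wild type rests on 1 pair, so calls are not given. RLM1 is one of the 66, and without it 17 of 65 were lower in rlm1 (56 in the pair-blocked fit). Without the dye, 11 of the 66 were higher and 18 lower in swi3 than in the wild type. Of all 5659 features, 215 were higher and 1265 lower there. A lower response in swi3 therefore need not mean a lower treated level: RLM1 was at 10.45 in treated swi3 and 10.44 in the treated wild type. When the genes were selected without a wild-type pair, the left-out pair gave medians of 1.63, 1.91 and 2.03, beside 0.205 to 0.217 in rlm1 and 0.58 to 0.63 in swi3. Responders were selected again in the fits without 1 array. Without untreated number 1 of rlm1 the median in rlm1 turned to -0.03, and 47 of 86 responders were lower in rlm1 and 16 in swi3. Without treated number 1 of rlm1 the median was 0.51. The count lower in rlm1 was 9 to 11 without any treated wild-type array, untreated wild-type number 1 or 3, or untreated rlm1 number 2 or 3. The count lower in swi3 was 14 without treated rlm1 number 1. The fixed Rlm1-linked list, which does not rest on this selection, had medians of 1.21, 0.09 and 0.52.

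**Figure D2:**
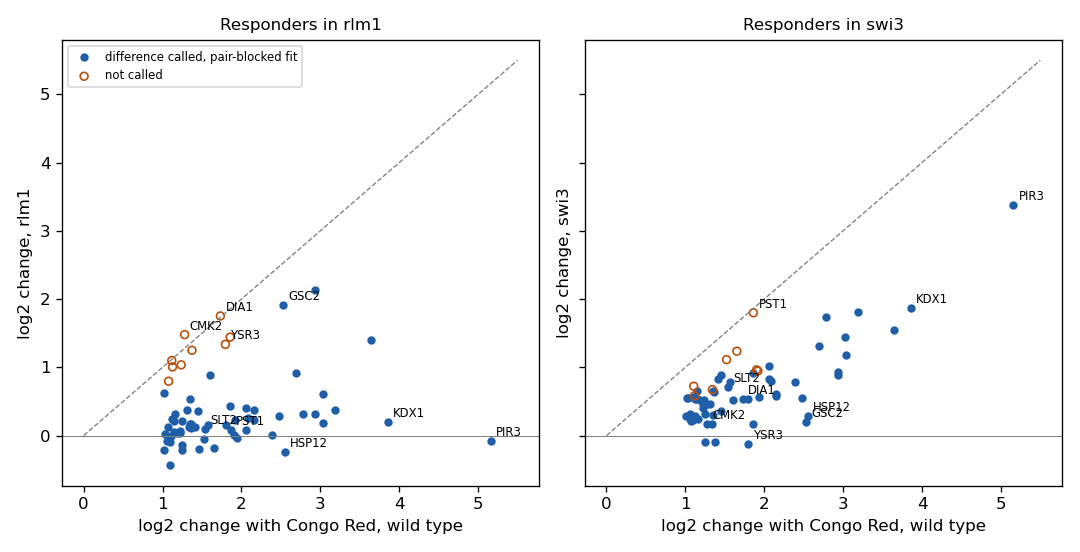
Log2 change with Congo Red of the 66 wild-type responders in the wild type (x axis) and in each mutant (y axis); filled points have a called difference in the pair-blocked fit, open points do not, and the dashed line marks equal changes. GSC2, DIA1 and CMK2 are at 1.91, 1.75 and 1.48 in rlm1 and at 0.20, 0.54 and 0.17 in swi3, while PST1 is at 0.08 in rlm1 and 1.80 in swi3.

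Calls in different strains overlapped. All 5 calls in rlm1 and all 9 in swi3 were among the 89 higher in the wild type, against 0.0786 and 0.142 for independent lists, and 0 were shared between the mutants, against 0.008. With the pair block, 24 higher and 4 lower calls were shared between the mutants, against 4.68 and 0.262 for independent lists. Of the lower responses, 3 were shared by rlm1 and swi3, against 0.019 for independent lists. The 3 were BAG7, a probe set with no gene name here and YPL088W, which neighbours RLM1. In the pair-blocked fit 115 lower and 54 higher were shared, against 9.80 and 4.07 for independent lists. In 100 simulations of unchanged groups with shared wild-type arrays, the mean shared counts were 0 in the planned fit and 0.04 and 0.03 in the pair-blocked fit, but unchanged groups have few calls to share, so these do not show what sharing the arrays adds at the observed numbers of calls. Across genes, which are not independent replicates, the differences had a correlation of 0.714 (simulated mean 0.339) and a covariance of 0.0617 (simulated mean 0.0070). The 3 wild-type arrays per group could not be split with 2 on each side, so part of the overlap may come from sharing them.

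Without the dye, rlm1 differed from the wild type in 4 features. RLM1 was lower (-4.47 ± 0.14, n = 3, adjusted p = 1.9e-11), a least estimate since its level of 4.78 in rlm1 was that of the background, as were YLR154C-H (-2.30 ± 0.40) and the histone deacetylase SIR2 (-0.90 ± 0.13), and RSC8, a subunit of the RSC chromatin remodelling complex, was higher (1.27 ± 0.21). SIR2 was no longer called after quantile normalization (-0.68, adjusted p = 0.224), median centring (-0.64, adjusted p = 0.355) or with the trended and robust prior (adjusted p = 0.057). YLR154C-H was not called without both number 1 arrays of rlm1 (-1.94, adjusted p = 0.094) or without any 1 of the 6 arrays compared, and RSC8 only kept its call without rlm1 number 1 among those 6. Restricted to the 2 groups, none of these 3 was called, and with ordinary least squares neither YLR154C-H nor RSC8 was. The median of all genes was -0.27 in this comparison, -0.01 after quantile normalization and -0.04 without the number 1 arrays of rlm1. Mating genes had 0 of 24 calls (1 lower adjusted over the list alone) and a median of -0.79 (-0.55 after quantile normalization). The mating list had adjusted p = 2.3e-06 and adjusted p = 0.829 with an estimated correlation. FIG1 was at -2.25 ± 0.76. Quantile normalization gave 8 higher and 14 lower, and leaving out the untreated wild-type number 1 or 2 or the rlm1 number 2 or 3 array left 1 call, against 7 without the number 1 arrays of rlm1.

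Without the dye, swi3 differed widely from the wild type. The difference between 3' and 5' control probe sets was also larger on these arrays (1.04, 0.83 and 1.26 on swi3 numbers 1 to 3, 0.76 to 0.80 in the wild type), so part of the changes may come from RNA quality. The phosphate transporter PHO84 was the furthest below the wild type (-8.55 ± 0.27, SE, n = 3, adjusted p = 1.3e-11), followed by SPL2 (-6.14), the acid phosphatases PHO11 (-5.04) and PHO5 (-4.67), the mating-type endonuclease HO (-4.57), the amino acid permease DIP5 (-4.48), ARO10 (-4.46), YBL005W-A (-4.39) and GPX2 (-4.18), with SWI3 itself at -6.29. The levels of SWI3, PHO84, SPL2, HO, DIP5, ARO10 and YBL005W-A in untreated swi3 were under 7, so these differences are least estimates. Among named genes, the largest increases were in HUG1 (3.80 ± 0.22) and RNR3 (2.77), both known from the DNA damage response, HBN1 (3.76), PRR2 (3.70), the proline permease PUT4 (3.69), RCK1 (2.90), the maltase MAL32 (2.71), MET2 (2.67), HSP12 (2.62) and YMR206W (2.62). The median of all genes was -0.41 and -0.05 after quantile normalization, so the group values below are given under both scales.

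Of 17 genes of the phosphate regulon, 15 were lower and 1 higher (16 and 1 adjusted over the list alone, median -2.15, and -1.68 after quantile normalization). The phosphate list had adjusted p = 2.2e-14, adjusted p = 0.557 with an estimated correlation and fry's adjusted p = 1.0e-06. Mating genes were lower in 15 of 24 cases (17 adjusted over the list alone, median -1.42 and -0.79), among them PRM4 (-2.92) and BAR1 (-2.91). For mating genes camera gave adjusted p = 0.0010 and adjusted p = 0.988 with an estimated correlation. Daughter-separation genes were lower in 9 of 14 cases (11 adjusted over the list alone, median -1.01 and -0.71), such as SCW11 (-2.03), PRY3 (-1.87), DSE1 (-1.85) and EGT2 (-1.56). The separation list had adjusted p = 2.0e-04 and adjusted p = 0.829 with an estimated correlation. Iron uptake genes were lower in 10 of 20 cases (12 adjusted over the list alone, median -2.01 and -1.38), including ARN2 (-3.59) and ENB1 (-3.28). The iron list had adjusted p = 0.052 (0.0035 after quantile normalization). Sulphur genes were higher in 10 and lower in 2 of 19 cases (10 and 2 adjusted over the list alone, median 1.10 and 1.41), such as MET3 and MET28 (both 2.25) and MET10 (1.45). For sulphur genes camera gave adjusted p = 9.1e-12 and adjusted p = 0.648 with an estimated correlation. Oxidative phosphorylation genes were higher in 7 and lower in 0 of 34 cases (3 higher adjusted over the list alone, median 0.40 and 0.62). The oxidative phosphorylation list had adjusted p = 7.3e-18 and adjusted p = 0.751 with an estimated correlation. Drug efflux genes were lower in 11 and higher in 3 of 21 cases (11 and 3 adjusted over the list alone, median -0.77 and -0.39), including QDR2 (-2.68) and PDR15 (-2.45). The drug efflux list had adjusted p = 0.387.

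Markers of alpha cells were lower in 4 of 4 cases and of sporulating cells in 13 of 22 (4 and 18 adjusted over the list alone), but their medians moved from -1.36 to -0.54 and from -0.81 to -0.07 with quantile normalization. Camera gave adjusted p = 0.0015 for each, adjusted p = 0.504 and adjusted p = 0.829 with an estimated correlation, and 0.148 and 0.628 after quantile normalization. Both lists served as checks for cells of other types, so lower values in them may come from the lower background of the swi3 arrays. Glucose-repressed genes were higher in 8 and lower in 6 of 30 cases (9 and 6 adjusted over the list alone, median 0.01 and 0.70 after quantile normalization). For this list camera gave adjusted p = 1.85e-05 and adjusted p = 0.758 with an estimated correlation. Of the 22 Rlm1-linked targets, 3 were higher and 3 lower in untreated swi3 (3 and 3 adjusted over the list alone), with a median of -0.13 that was 0.14 after quantile normalization, including CWP1 (1.01), CRH1 (0.71), PST1 (-1.83) and GSC2 (-0.88, not called without wild-type untreated number 3, adjusted p = 0.064). RLM1 was 0.68 ± 0.14 higher.

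In all, 215 features were higher and 1265 lower in untreated swi3 (109 and 468 by at least 2-fold). Of these, 5 and 201 had mean levels under 7 in both groups. The share of lower calls was 85.5%, and 50.4% after quantile normalization (793 higher, 807 lower); 214 of the higher and 648 of the lower calls were shared between both scalings. Leaving out any of the 6 arrays lowered the 1480 calls to between 739 (without wild-type untreated number 2) and 880 (without swi3 untreated number 2), and leaving out both rlm1 number 1 arrays raised them to 4086.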

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

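The tests of technical explanations below were chosen after the results had been seen; the counts over other splits of the arrays were planned before.

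Responses that differed between strains by the test of the difference are listed with their log2 values. In rlm1 against the wild type, 18 features differed: PIR3 (-5.24), KDX1 (-3.67), BAG7 (-2.86), YPL088W (-2.62), a probe set with no gene name here (-2.42), YNR066C (-1.98), SHH3 (-1.98), PRM10 (-1.93), YPK2 (-1.90), PST1 (-1.79), YPS3 (-1.78), CWP1 (-1.54), SLT2 (-1.44), FLC2 (-1.20), RLM1 (-1.15), ASK10 (-1.13), CRH1 (-0.94) and MSG5 (-0.93). In swi3 against the wild type, 6 did: GSC2 (-2.33), YPL088W (-2.05), YSR3 (-1.92), BAG7 (-1.86) and 2 probe sets with no gene name here (-2.0 and -1.58). Between the mutants, 1 did: PIR3 (3.46). The difference in RLM1 is fixed by its deletion, and 17 of the 18 remain without it.

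The smaller response of the wild-type responders in both mutants was set against technical explanations. Selection on the wild-type arrays would have let the left-out wild-type pairs fall to the level of the mutants, but the lowest of their medians was 1.63, against at most 0.63 in a mutant. Compressed signal would have narrowed the spread across genes on the mutant arrays, but the lowest ratio to the wild type was 1.00 and the highest 1.18. The left-out medians argue against selection. The ratios compare spreads of levels, which the lower background of the swi3 arrays (below) can widen. They therefore cannot decide on compressed changes. An offset shared by all arrays of a strain cancels, as the response is taken within each strain, and the median of the responders was 1.39 to 1.63 in the wild-type pairs and at most 0.70 in a pair of a mutant. A difference of genotype remains open as a hypothesis, and the labels do not say whether the treatment of the strains was done side by side. RNA quality stays open for swi3, where the difference between 3' and 5' control probe sets was smaller with the dye. In its number 2 pair, where that difference was 0.83 and 0.80, the median of the responders was 0.44.

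Of 100 splits of the arrays, the real one included, 5 gave at least as many calls as the 18 for rlm1 against the wild type in the response (highest other 67), so chance was not excluded for that count. Of the 4 others, 2 put the number 1 arrays of rlm1 in different strains. Chance was not excluded either for the 6 calls for swi3 (6 of 100 with the real one, highest other 2929) and the 1 call between the mutants (18 of 100 with the real one, highest other 2694), where 13 of the 17 others parted the number 1 arrays in that way. The splits moved arrays between strains separately among untreated and treated arrays. A split can therefore take in the difference between the strains without the dye (1480 calls for untreated swi3). The splits with 2929 and 2694 calls may do so, and none of these counts can decide on chance in the response. In the pair-blocked fit, splits of whole pairs between strains gave at most 0 calls, against 596, 255 and 101, but they number 10 and cannot give a share under 0.05.

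For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real and the highest other count were 116 and 0 for Congo Red in wild type (1 split as large, the real one), 9 and 0 in swi3 (1), 4 and 0 for untreated rlm1 (1), and 1480 and 0 for untreated swi3 (1). For Congo Red in rlm1 they were 5 and 3736: 5 splits were as large, and the 4 others all put both number 1 arrays in the same group. Among the 4 splits that part every pair, the highest other count was 0.

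The excess of lower calls in untreated swi3 was set beside the background of the arrays. Of the 47 reporter probe sets, 36 stayed under 7 on every array, a level set after the values were seen, and were taken as background. All 36 were lower in untreated swi3 than in the untreated wild type, by a median of -0.59. This is what a lower background and scale of the swi3 arrays would give. Of the 1265 lower calls, 201 had mean levels under 7 in both groups and 351 in at least 1. Most thus lay at 7 or above in both groups, and how far a lower background reaches at such levels was not tested. The even split after quantile normalization decides nothing, as that step makes the distributions match. A true fall of many transcripts per cell remains open, since the arrays carry no measure of RNA per cell. The phosphate regulon kept a median of -1.68 after quantile normalization.

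The number 1 arrays of rlm1 stood apart from the others of their groups, with medians of 9.27 and 9.28. A scale difference alone would vanish after quantile normalization, but their mean correlation with the other rlm1 arrays of the same group was then 0.968, below the lowest within any wild-type or swi3 group (0.976), which argues against it as the whole cause. Lower RNA integrity stays open: the difference between 3' and 5' control probe sets was at least 1.03 on these arrays, and 2 swi3 arrays, with medians near those of their group, were as high. No biological explanation was tested, as the labels do not set these arrays apart.

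Signals also appeared in control probe sets, which the comparisons leave out. A reporter probe set was 8.62 and 8.49 higher in untreated and treated rlm1 and 8.62 and 8.53 higher in untreated and treated swi3 than in the untreated wild type, where its level was 5.06 ± 0.14 (SD, n = 3). What this probe set matches in the mutants was not tested, and a marker gene of the deletion strains stays open. The 25S ribosomal RNA probe sets were 2.91 and 2.98 higher in untreated rlm1 than in the untreated wild type. With Congo Red their levels were 12.03 ± 0.70 and 11.61 ± 0.99 in rlm1 against 8.94 ± 0.78 and 8.70 ± 0.63 in the wild type. In swi3 they were 11.58 ± 1.28 and 10.74 ± 1.55 without the dye and 7.97 ± 0.59 and 7.13 ± 0.66 with it. The margin of 2.5 used to pick such probe sets was set after their levels had been seen, and a slightly larger one would have left the ribosomal RNA sets out.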

How the results depend on the processing

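The fits with the replicate block within strain and those without both number 1 arrays of rlm1 were chosen after seeing the data; all other alternatives were fixed before the data were examined. The cause of each change was not tested, except that leaving out arrays or groups changes the shared spread. Signal over background limits the weakest probe sets; 8 features were removed for low signal.

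With the fit restricted to the groups compared, calls were 1013 for Congo Red in wild type and 0 in rlm1. They were 9 and 59 for the response of rlm1 and swi3 against the wild type, and 0 between the mutants' responses. Untreated rlm1 and swi3 had 1 and 3670. Responders were selected again in each fit, and of 99 here, 9 were lower in rlm1 and 41 in swi3. Repeated quantile normalization gave 982, 33 and 56 for Congo Red in wild type, rlm1 and swi3. It gave 200 and 100 for the response of rlm1 and swi3 against the wild type, 17 between the mutants and 22 for untreated rlm1. Of its 95 responders, 61 and 55 were lower in rlm1 and swi3, and of the 66 of the planned fit, 51 and 47. Median centring gave 596, 26, 43, 87, 51 and 12 in the same order up to the mutants, with 49 and 35 of 93 responders lower. Calls between the mutants' responses were 3 with the trended and robust prior and 0 with ordinary least squares, which gave 2 for untreated rlm1. Leaving out both number 1 arrays of rlm1 gave 1061, 20 and 138 for Congo Red, 170 and 103 for the mutants' responses against the wild type, 13 between them, 7 and 4086 for untreated rlm1 and swi3, and 100 responders, with 61 and 53 lower in rlm1 and swi3. No filter, the stricter filter and all probe sets kept every count within 1.5 times.

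The replicate block as the replicate number gave 212 and 8 for Congo Red in wild type and rlm1 and 2343 for untreated swi3. It gave 36 and 14 for the responses of rlm1 and swi3 against the wild type and 3 between them. Of its 89 responders, 34 and 14 were lower in rlm1 and swi3. The replicate block within strain gave 1856, 99, 409, 596, 255 and 101 for the 3 Congo Red comparisons and the 3 differences of responses, and 100 responders, 81 lower in rlm1 and 77 in swi3. With quantile normalization as well, this block gave 2282, 125, 385, 915, 527 and 125, and 102 responders, 89 and 93 lower. The block within strain could not be fitted for the untreated comparisons, as pairs lie within a strain. It ended none of the 72 calls of named genes and 2 of the 62 calls of lists that it could test. Of all 178 calls of named genes, quantile normalization ended 17 besides the 2 it reversed, median centring 25, the fit restricted to the groups compared 22, ordinary least squares 19, the trended and robust prior 8 and leaving out both number 1 arrays of rlm1 1. The stricter filter ended 3 of the 176 it tested, the block by number 0, and fits without 1 array 323 of 1188.

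Camera passed for 83 of 200 list tests as planned, 0 with an estimated correlation and 9 with fry. Those with fry were Rlm1-linked targets for Congo Red in wild type and swi3 and for rlm1 against the wild type in the response. The others were 6 lists in untreated swi3 (phosphate, mating, separation, alpha and sporulation markers, and genes deleted in BY4741). Both sets of markers and the deleted genes were checks. A pass for genes absent from the strain cannot be a change in their transcripts, so passes in untreated swi3 can arise without one. Fry turned the direction of 10 tests, as it takes absolute changes where camera takes them relative to other genes: for untreated rlm1 ribosome biogenesis (adjusted p 0.949), iron uptake (0.983), oxidative phosphorylation (0.944), sporulation markers (0.895) and ribosomal proteins (0.983), and for untreated swi3 Rlm1-linked targets (0.983), mannoproteins (0.895), general stress (0.895), osmotic stress (0.983) and ribosomal proteins (0.683). Quantile normalization turned ribosomal proteins (adjusted p 0.341), CDA1 (log2 0.12, adjusted p 0.782) and MET17 (log2 0.080, adjusted p 0.645) in untreated swi3. Leaving out rlm1 untreated number 1 turned ribosome biogenesis with Congo Red in rlm1 (adjusted p 0.637) and the responders' median in rlm1 (-0.027, and 0.514 without treated number 1). That list's adjusted p ranged down to 4.0e-06 without untreated number 3.

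Over fits without each array in turn, calls ranged from 62 to 74 for Congo Red in wild type, 4 to 9 in rlm1, 3 to 5 in swi3, 9 to 53 and 4 to 5 for the responses of rlm1 and swi3 against the wild type, 0 to 4 between them, and 1 to 3 and 739 to 880 for untreated rlm1 and swi3. Responders numbered 53 to 86, with 9 to 47 lower in rlm1 and 4 to 16 in swi3, and 80 to 93 list tests passed.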

Other observations

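The test of the Crz1 list below was chosen after the responses of GSC2, CMK2 and related genes had been seen.

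The genes named here were chosen after their values were seen. Several responders of the wild type had similar values in rlm1 and smaller ones in swi3. With Congo Red, DIA1 was at 1.73, 1.75 and 0.54 in the wild type, rlm1 and swi3, YSR3 at 1.80, 1.34 and -0.12, YPT53 at 1.37, 1.25 and -0.09, CMK2 at 1.28, 1.48 and 0.17, and RCN2, an inhibitor of calcineurin, at 1.13, 1.01 and 0.29. Among the 66 responders the pair-blocked fit called 7 with a smaller response in swi3 than in rlm1 and 23 with a larger one.

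A hypothesis is that some of these genes are targets of calcineurin and its transcription factor Crz1. This arm of the response may then rest on Swi3 more than on Rlm1. The hypothesis was tested on 9 members of a list of textbook Crz1 targets that had not been used to form it. Their median difference between swi3 and rlm1 in the response was -0.29, from medians of 0.35 in the wild type, 0.37 in rlm1 and 0.08 in swi3. In the pair-blocked fit camera gave an exploratory limma p of 1.38e-06 with the preset correlation and 0.0435 with an estimated one, and 1 of the 9 was called by itself, SCW10 (-0.35). CHS1, a member that had been seen before, went the other way (0.28). The 9 as a set thus had a smaller response in swi3 than in rlm1. However, ENA5, CRZ1, MEP1 and PMR1 among them were not called in the wild type in the pair-blocked fit. SCW10 and KRE6 are also in the beta-glucan list tested above. DIA1, YSR3 and YPT53 are not on the Crz1 list, so the test cannot say whether they are targets. RNA quality stays open for swi3. With 3 arrays per group, and with rlm1 number 1 arrays that stand apart, the result needs an independent measurement.

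YPL088W, which neighbours RLM1 in assembly R64, had log2 levels of 9.39 ± 0.10 in the untreated wild type and 9.49 ± 0.11 in untreated rlm1 (SD, n = 3), and 12.33 and 9.81 with Congo Red. Whether its lower response in rlm1 rests on the deletion next to it was not tested.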
